A study of Homo sapiens with 12 samples.

How the data were processed

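RNA of human proximal tubular epithelial cells was sequenced from 12 libraries in 4 groups of 3 (Normoxia, Hypoxia, Vehicle and Cytokine), and the groups were taken from the sample titles, since both control groups carry the same treatment label. Per the labels' protocols, polyadenylated RNA was used and treatments lasted 12 hours. The authors deposited 4 tables, 1 per comparison and annotation, in the column layout of Cuffdiff per the file headers. The submitters' processing notes name STAR, Cufflinks 2.1.1, Cuffdiff and the build hg19, without versions of the other tools and without saying which step each did. In each comparison, 1 table holds known genes with GENCODE noncoding genes and the other known genes with loci of a lincRNA catalogue, as the identifiers show; the GENCODE release is not given in the sources used here.

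Each row of the authors' tables gives an FPKM value (fragments per kilobase of transcript, scaled to the sequenced fragments) for each of 2 groups, per the file headers. The log2 fold change is deposited as the second group over the first, and the first group was taken to be Normoxia or Vehicle from the order of names in the table titles, since the column headers give only positions. The deposited test statistic is a score without a fixed range, and the deposited p-value and q-value come from the authors' comparison of both groups, per the file headers. The significant mark of the tables follows q under 0.05 with 0 exceptions. The smallest p-value in the authors' tables is 5e-05, so many genes share 1 smallest q-value, 0.00038 in hypoxia and 0.000322 with cytokines. Tables of different comparisons were normalized separately by the authors.

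The tables hold no value per library, so no count test, replicate spread or fit of library values could be made, and all tests of single genes are the authors'. The read depth is unknown, and low values showed no steps of whole reads: among 1377 genes under 0.05 FPKM in both hypoxia groups, the fullest bin of the group ratio, 0.01 wide on the log2 scale, held 52. The score does not follow the deposited p-value as a normal statistic would. The normal deviate of p was a median of 1.71 times the score in hypoxia and 1.70 times with cytokines. The planned test of the difference between both responses, conditional on such agreement, was therefore not run as planned. A version with standard errors from the log2 fold change over the score, which are wider, was added after seeing the data. On 12589 simulated genes with 200 changed, it found 0% of changes of 1 on the log2 scale and 55.5% of changes of 2, with 6.72% false calls. The simulated noise was drawn from those same standard errors, so the rate of false calls in the data is unknown.

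Rows on the Y chromosome and XIST were left out, since such genes describe the donor. A gene counted as tested when its status was OK in the table. For lincRNAs only the catalogue loci of the second table were counted, a restriction stated after seeing that the table also holds known genes. Fixed gene lists were described by counts of called members, counts with Benjamini-Hochberg adjusted over the list alone, and the median log2 fold change of members with at least 1 FPKM in either group. That median was placed among 10000 random lists of the same size matched on mean log2 FPKM in 10 bins, with FPKM raised to at least 0.01 for the matching. Tested on simulated data with 12711 genes, 4% of 100 unchanged lists fell outside the middle 95% and 100% of 100 lists raised by 1 on the log2 scale lay above it. The simulated genes varied independently, so this does not cover lists whose members vary together. Overlaps were set against the number for independent lists, with a one-sided Fisher's exact test. The 2 comparisons have separate control groups in the labels.

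Genes were named by a rule fixed before the data were examined. It takes, per comparison and from the GENCODE table, the 10 largest and 10 smallest finite log2 fold changes among genes with q under 0.05 and at least 1 FPKM in the higher group. It adds the 5 largest and 5 smallest among lincRNA loci with at least 0.5 FPKM, such genes called in both comparisons, and from each list up to 4 called members with the largest change and the most abundant member not called. Genes listed at 0 in a group were counted and not ranked. Genes named outside the rule were named after their values were seen. Among them are KISS1R, LOC101927318, ZNF395, CA9, SLC2A3, S1PR3, SEMA5B, PPL and KBTBD11. Some genes that the rule names, and 1 test that needs one of them, are not reported here. Alternatives tried were a q threshold of 0.01, a log2 fold change of at least 1 in size, a filter at 1 FPKM, pseudocounts of 1 and 0.1, centring on the median, p values from the score, the other annotation table and chance numbers matched on expression.

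Coordinates are hg19 as in the authors' tables. Table starts count from 0, since end minus start equals the RefSeq gene length in GRCh38 for 1855 of 14209 genes with a length and end minus start plus 1 for 238, although lengths can differ between builds, so 1 was added to each printed start. An interval can cover several overlapping genes. Whether the authors' counting used strand is not given in the sources used here, so reads of overlapping and antisense genes may not be separable, nor those of near copies such as metallothioneins and HLA genes. Scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.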

Results

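Polyadenylated RNA was sequenced from human proximal tubular epithelial cells, the cells that line the first segment of the kidney tubule and reabsorb most of the filtrate. The 12 libraries fall into 4 groups of 3 libraries each: Normoxia, Hypoxia (0.1% oxygen), Vehicle and Cytokine (IFN-gamma at 20 ng/mL with TNF-alpha and IL6 at 50 ng/mL each). Treatments lasted 12 hours. The comparisons ask how the transcriptome of these cells responds to low oxygen and to inflammatory cytokines, each against its own control group. Values are the authors' FPKM, 1 value per group, so no spread between libraries could be computed here and the read depth of the libraries is unknown. All tests of single genes are the authors' own q values, and a gene is said to have risen or fallen when its q value was under 0.05. The labels do not say whether the 3 libraries of a group came from separate donors or cultures, so these q values measure only the spread between the libraries, which may be technical.

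After 12 hours of hypoxia, genes of glycolysis and other targets of the hypoxia-inducible factors (HIF) rose together, while 11 of 20 tested genes of the unfolded protein and stress response and 9 of 20 of cholesterol synthesis and uptake fell. ANGPTL4, a secreted inhibitor of lipoprotein lipase, went from 0.598 to 44.6 FPKM (log2 fold change 6.22, q = 0.00038), and NDRG1 from 90.5 to 1559 FPKM (4.11, q = 0.00038), in the authors' deposited table. The tight junction protein CLDN2 went the other way, from 47.1 to 4.07 FPKM (log2 fold change -3.53, q = 0.00038), as did the transferrin receptor TFRC, from 57.9 to 7.47 FPKM (-2.95, q = 0.00038), in the authors' deposited table. Of 12959 genes tested with the GENCODE noncoding annotation, 1939 rose and 2081 fell, which is 31.0% of those tested. With a log2 fold change of at least 1 in size, 673 rose and 517 fell. When p values were taken from the deposited test statistic instead, an alternative chosen after seeing the data, 666 rose and 580 fell.

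By size of change, the 10 genes highest in hypoxia in the authors' deposited table were ANGPTL4 (19:8429011-8439259 in hg19), the nuclear receptor RORA (log2 fold change 5.91), NIM1K (5.64), HMHA1 (4.88), SEC14L5 (4.70), CLEC2B (4.65), C4orf47 (4.25), FAM115C (4.24), NEURL3 (4.16) and LOC154761 (4.15). All 10 stood under 1 FPKM in Normoxia in the authors' deposited table, with NIM1K at 0.0464 FPKM and C4orf47 at 0.445 FPKM, so their fold changes rest on low control values. The 10 lowest in the authors' deposited table were AC137934.1 (-5.02, ENSG00000260923.1), CLDN2 (X:106143293-106174091), the microRNA host gene MIR22HG (-3.14, ENSG00000186594.8), the cytochrome P450 enzyme CYP1B1 (-3.09), TFRC, the ribosome biogenesis factor RRS1 (-2.87), RPS6KL1 (-2.64), the fatty acid transporter SLC27A4 (-2.55), TNFRSF11B (-2.50) and PIK3R3 (-2.49). AC137934.1 had a test statistic of only -0.97 beside its q of 0.00387 in the authors' deposited table, so its fall is uncertain. MIR22HG (-1.40) and HMHA1 (1.83) also had small test statistics in the authors' deposited table, so their changes are uncertain as well. FAM115C and LOC154761 are related sequences whose reads may not be separable. MIR22HG has a second record at the same locus, which was not tested and went the other way (0.00252 to 0.317 FPKM) in the authors' deposited table. KISS1R, the 1 gene called from a Normoxia value listed at 0, reached 1.06 FPKM in Hypoxia in the authors' deposited table and has no fold change.

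In the glycolysis and glucose uptake list, 17 of 21 tested members rose with hypoxia and 0 fell (19 and 0 adjusted over the list alone), by the authors' deposited table. HK2, which phosphorylates glucose, rose from 6.90 to 67.6 FPKM (log2 fold change 3.29), PFKFB4 by 3.13, ENO2 by 2.63 and PDK1, which restrains entry of pyruvate into the mitochondrion, by 2.39 on the log2 scale in the authors' deposited table. GAPDH, the most abundant member that was not called, stood at 5357 FPKM in Normoxia and 9760 FPKM in Hypoxia (q = 0.103) in the authors' deposited table. Among 33 other HIF target genes, 32 rose and 1, TFRC, fell (32 and 1 adjusted over the list alone). They were led after ANGPTL4 and NDRG1 by PPFIA4 (3.82) and the collagen cross-linking enzyme LOX (3.73) in the authors' deposited table. The list medians were 1.28 for glycolysis and 2.49 for the other HIF targets, each at percentile 100 of 10000 random lists matched on expression.

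Stress and lipid lists moved the other way under hypoxia. Among genes of the unfolded protein and integrated stress response, 4 rose and 11 fell of 20 tested (4 and 11 adjusted over the list alone), with a median of -0.65 at percentile 0 of the random lists. SDF2L1 (-2.41), CHAC1 (-2.05) and the chaperone HSPA5 (158.8 to 51.2 FPKM, -1.63) fell, PPP1R15A rose (1.59), and HSP90B1 was not called (-0.36, q = 0.110), in the authors' deposited table. Of 20 cholesterol synthesis and uptake genes, 0 rose and 9 fell (0 and 10 adjusted over the list alone), with a median of -0.36 at percentile 0.12. HMGCS1 (-1.10), IDI1 (-0.95) and FDFT1 (-0.94) fell and MSMO1 did not pass the test (-0.33, q = 0.121) in the authors' deposited table. Of 23 oxidative phosphorylation subunits, 0 rose and 4 fell (0 and 3 adjusted over the list alone), with a median of -0.14 at percentile 14.2. The 4 were ATP5A1 (-0.55), NDUFS1 (-0.52), UQCRFS1 (-0.50) and NDUFB3 (-0.45), while ATP5B stood at -0.21 (q = 0.360), in the authors' deposited table. Metallothioneins, small metal-binding proteins, rose in 4 of 5 tested members with 0 lower (5 and 0 adjusted over the list alone), from MT1X (1.55) and MT1E (1.15) to MT1F (0.65) and MT1M (0.58), with MT2A at 0.44 (q = 0.0565), in the authors' deposited table. These genes are near copies of each other.

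Medians of the immune and cell death lists stayed within the middle 95% of the random lists in hypoxia. Percentiles were 47.1 for interferon-stimulated genes, 3.5 for chemokines and cytokines, 95.4 for NF-kB targets, 14.3 for MHC class I and 34.4 for class II. They were 54.5 for complement and acute phase and 40.4 for cell death and inflammasome genes. Of 31 tested interferon-stimulated genes, 3 rose with hypoxia and 7 fell (3 and 7 adjusted over the list alone). The fallen members included SOCS1 (-1.53), WARS (-1.10) and GBP1 (-0.70), and ISG15 stood at 0.09 (q = 0.732), in the authors' deposited table. Of 12 tested chemokines and cytokines, 0 rose and 3 fell (0 and 3 adjusted over the list alone). These were CXCL1 (-2.17), CCL2 (-1.72) and CXCL2 (-1.57), with IL18 at -0.32 (q = 0.149), in the authors' deposited table. NF-kB target genes gave 6 higher and 2 lower of 19 (6 and 2 adjusted over the list alone). IER3 (1.72), TNIP1 (1.45) and BIRC3 (1.34) rose, the adhesion molecule VCAM1 fell (-1.92) and SOD2 stood at 0.21 (q = 0.441), in the authors' deposited table. Antigen presentation by MHC class I had 3 members higher and 3 lower of 17 (3 and 3 adjusted over the list alone). Among them were HLA-E (0.81), TAP2 (17.3 to 8.67 FPKM), PSME2 (-0.69) and NLRC5 (-0.65), with B2M at 0.17 (q = 0.516), in the authors' deposited table. MHC class II presentation had 0 calls among 4 tested members (0 and 0 adjusted over the list alone), with CD74 at -0.17 (q = 0.478) in the authors' deposited table. Complement and acute phase genes had 2 higher and 1 lower of 11 (1 and 1 adjusted over the list alone). SERPING1 (0.55) and C1R (0.43) rose and CD55 (-0.55) fell, with CD46 near 126.0 FPKM in both groups (q = 0.997), in the authors' deposited table. Cell death and inflammasome genes had 0 higher and 3 lower of 14 (0 and 3 adjusted over the list alone). They included BAK1 (-0.84) and RIPK1 (-0.68), with TNFRSF10B at 0.37 (q = 0.0992), in the authors' deposited table.

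Lists for the state of the tubule cell were mixed in hypoxia. Of 12 tested tubular injury markers, 3 rose and 3 fell (3 and 3 adjusted over the list alone). KRT19 (0.92), VIM (0.92) and SOX9 (0.54) rose, VCAM1 was among those that fell, and KRT18 stood at -0.16 (q = 0.751) in the authors' deposited table. Proximal tubule identity genes had 4 higher and 1 lower of 11 tested (4 and 1 adjusted over the list alone), and the other 16 of 27 members were not tested. The gluconeogenic enzyme PCK1 rose from 0.142 to 1.40 FPKM (3.30), MME rose (0.96), the water channel AQP1 fell from 0.965 to 0.255 FPKM (-1.92), and PAX8 stood at -0.03 (q = 0.921), in the authors' deposited table. Matrix and TGF-beta response genes had 2 higher and 4 lower of 14 (2 and 4 adjusted over the list alone), the lower ones being THBS1 (-1.82), CTGF (-1.23), ITGB6 (-0.92) and CYR61 (-0.86), with FN1 at -0.09 (q = 0.783), in the authors' deposited table. Among DNA replication and mitosis genes, 1 rose, MCM2 (0.49), and 1 fell, CDC20 (-0.48), of 27 (1 and 1 adjusted over the list alone), and UBE2C stood at 0.37 (q = 0.0649), in the authors' deposited table. For p53 target genes, 2 rose and 2 fell of 18 (2 and 2 adjusted over the list alone). These were DDB2 (0.97), SESN1 (0.52), PLK3 (-0.92) and TP53INP1 (-0.50), with CDKN1A at -0.15 (q = 0.522), in the authors' deposited table.

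Markers of other kidney and blood cells, like those of the proximal tubule, were mostly not tested in the hypoxia comparison. Of the distal nephron markers 3 of 11 were tested and 0 called (0 and 0 adjusted over the list alone), with SCNN1A at -0.52 (q = 0.555), by the authors' deposited table. Of the tested markers of fibroblasts (3), endothelium (2), leukocytes (2) and podocytes (1), 1 in each list was called, with the same counts adjusted over the list alone, by the authors' deposited table. These were PDGFRB (0.85, to 2.45 FPKM), CDH5 (-1.09, to 1.24 FPKM), CD14 (-2.30, to 0.472 FPKM) and PODXL (-0.65, to 7.02 FPKM) in the authors' deposited table. ACTA2 (0.47, q = 0.305), ESAM (0.31, q = 0.477) and CD68 (0.23, q = 0.390) did not pass the test in the authors' deposited table, and WT1 was not tested.

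With cytokines, nearly all tested members of the interferon, antigen presentation, NF-kB and chemokine lists rose, as did 10 of 14 in the complement and acute phase list. CXCL10, a chemokine induced by interferon, went from 0.640 to 5419 FPKM (log2 fold change 13.05, q = 0.000322), and the tryptophan-degrading enzyme IDO1 from 0.110 to 955.6 FPKM (13.08, q = 0.00443), in the authors' deposited table. METTL7A fell from 3.70 to 0.135 FPKM (-4.78, q = 0.000322) in the authors' deposited table. Of 13001 genes tested, 2455 rose and 1934 fell, which is 33.8% of those tested, and with a log2 fold change of at least 1 in size these counts were 1316 and 858. When p values were taken from the deposited test statistic instead, 1212 rose and 508 fell, and at a q threshold of 0.01 the number that fell was 1235.

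By size of change, the 10 highest genes with cytokines in the authors' deposited table were IDO1 (8:39771328-39786309 in hg19), CXCL10, the ubiquitin-like protein UBD (12.78), CXCL11 (12.51), the B cell factor TNFSF13B (10.14), HLA-DRA (9.58), the somatostatin receptor SSTR2 (8.37), CCL2 (8.31), the protease CTSS (0.354 to 90.7 FPKM) and LMO2 (7.88). CXCL10 and CXCL11 are given 1 shared interval in the authors' deposited table (4:76932333-77033955). The lowest were RP11-706J10.1 (-5.85, ENSG00000254300.1), METTL7A, VAV3 (-4.38), RP1-60O19.1 (-4.05, ENSG00000235142.3), the amino acid transporter SLC43A1 (-3.99), LMOD1 (-3.91), PADI3 (-3.89), RASSF10 (-3.41), C14orf105 (-3.34) and RAB26 (-3.27) in the authors' deposited table. RP11-706J10.1 overlaps the lincRNA locus linc-ZFHX4-1, which is named below with a smaller fall. A further 33 genes rose from a Vehicle value listed at 0, and 1, LOC101927318, fell to a value listed at 0. Among the former, named after their values were seen, APOL4 reached 18.5 FPKM, GBP7 10.9 FPKM, CCL4 7.88 FPKM and the interferon IFNL3 2.42 FPKM in the authors' deposited table.

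Of 35 interferon-stimulated genes, 33 rose with cytokines and 0 fell (33 and 0 adjusted over the list alone), with a median log2 fold change of 4.92 at percentile 100 of the random lists. GBP4 rose from 1.20 to 265.3 FPKM (7.79), whereas CXCL9 went from 0.0162 to 131.1 FPKM and still did not pass the test (q = 0.386), in the authors' deposited table. All 17 members of MHC class I presentation rose (17 and 0 adjusted over the list alone, median 2.59). Among them were the peptide transporters TAP1 (4.93) and TAP2 (3.60), the immunoproteasome subunit PSMB9 (3.42) and HLA-E (3.18), in the authors' deposited table. All 10 members of MHC class II presentation rose (10 and 0 adjusted over the list alone, median 5.98). Among them were HLA-DQB1 (7.59), HLA-DRB1 (7.44) and CIITA, the transactivator of the class (6.29), in the authors' deposited table. HLA genes share sequence and differ between people, so their levels are uncertain.

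All 19 NF-kB target genes rose (19 and 0 adjusted over the list alone, median 3.33). Among them were IL32 (7.28), the feedback inhibitor TNFAIP3 (6.96), TRAF1 (5.81) and ICAM1 (34.9 to 1145 FPKM, 5.04), in the authors' deposited table. Of 18 tested chemokines and cytokines, 16 rose and 1, IL18, fell (16 and 1 adjusted over the list alone). TNFSF10 rose by 6.28 and CCL5 by 5.89 (31.8 to 1882 FPKM), and IL7 was not called (0.0559 to 1.71 FPKM, q = 0.170), in the authors' deposited table. Complement and acute phase genes rose in 10 of 14 with 0 lower (10 and 0 adjusted over the list alone, median 3.25). C1S (7.67), SAA2 (6.27), SAA1 (6.26) and CFB (6.03) led, and CD46 stood at 0.03 (q = 0.930), in the authors' deposited table. SAA1 and SAA2 are near copies whose reads may not be separable. Cell death and inflammasome genes rose in 15 of 18 with 0 lower (16 and 0 adjusted over the list alone, median 2.12). The necroptosis effector MLKL (4.55), IFI16 (3.84), CASP4 (3.39) and CASP1 (3.35) rose most, and PYCARD stood at 0.45 (q = 0.118), in the authors' deposited table.

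Genes of the hypoxia lists also rose with cytokines. In the glycolysis list 14 of 21 rose and 0 fell (14 and 1 adjusted over the list alone). HK2 (2.40), HK1 (1.60), PFKFB4 (1.48) and PGAM1 (1.31) rose most, and GAPDH stood at 0.37 (q = 0.350), in the authors' deposited table. Of 33 other HIF targets, 24 rose and 1, ZNF395, fell (25 and 1 adjusted over the list alone). The risen members included ANGPTL4 (3.01), INSIG2 (1.97) and PPFIA4 (1.79), with PLOD2 at 0.41 (q = 0.150), in the authors' deposited table. The medians were 1.05 at percentile 99.99 and 0.88 at percentile 100 of the random lists. HIF1A, the oxygen-regulated HIF subunit, is outside the lists and was named after its values were seen. Its RNA rose from 82.6 to 180.8 FPKM with cytokines (1.13, q = 0.000322) and fell from 131.2 to 45.9 FPKM in hypoxia (-1.52, q = 0.00038), in the authors' deposited tables. Its protein was not measured here. Of 20 unfolded protein and stress response genes, 10 rose and 1 fell (11 and 1 adjusted over the list alone, median 0.59, percentile 99.8). ATF3 (3.33), XBP1 (1.88), HSPA5 (1.32) and PPP1R15A (1.12) led, and HERPUD1 stood at 0.39 (q = 0.137), in the authors' deposited table.

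Of 27 DNA replication and mitosis genes, 1 rose with cytokines, BUB1 (0.64), and 7 fell (1 and 6 adjusted over the list alone). Among them were E2F1 (-0.85), CENPF (-0.79) and RRM2 (-0.60), with UBE2C at 0.01 (q = 0.984), in the authors' deposited table. The median of that list was -0.25 at percentile 0 of the random lists, which themselves had a median of 0.25. Cholesterol genes had 3 higher and 4 lower of 20 (3 and 4 adjusted over the list alone, median -0.09, percentile 0.17). The random lists matched to them had a median of 0.24. The low percentile therefore places a nearly unchanged list below lists that mostly rose, and does not show a fall of the list. STARD4 (1.58) and INSIG1 (1.20) were higher, MVK (-0.96) was lower and FDPS stood at 0.01 (q = 0.976), in the authors' deposited table. Of 18 p53 targets, 5 rose and 5 fell (6 and 5 adjusted over the list alone), the largest called changes being BBC3 (2.86), FAS (2.27), PLK3 (1.35) and TNFRSF10B (0.84), with CDKN1A at 0.43 (q = 0.0790), in the authors' deposited table. Oxidative phosphorylation subunits had 2 higher and 0 lower of 23 (0 and 0 adjusted over the list alone), SDHA (0.52) and COX7A2 (0.50), with ATP5B at -0.05 (q = 0.895), in the authors' deposited table. Of 5 tested metallothioneins 1 rose, MT2A (1.24), and 0 fell (1 and 0 adjusted over the list alone), and MT1E stood at -0.08 (q = 0.808), in the authors' deposited table.

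Proximal tubule identity genes had 3 higher and 4 lower of 9 tested with cytokines, 18 not tested (3 and 4 adjusted over the list alone), with a median of -0.49 at percentile 0.87. The cation transporter SLC22A2 (-1.98), FBP1 (-1.69) and GPX3 (-1.02) fell, while PDZK1 went from 17.7 to 3.22 FPKM without passing the test (q = 0.402), in the authors' deposited table. Tubular injury markers had 5 higher and 1 lower of 12 (5 and 1 adjusted over the list alone). VCAM1 (3.41), VIM (1.14) and TIMP1 (0.87) rose, KRT19 fell (204.6 to 102.0 FPKM) and KRT18 stood at -0.41 (q = 0.472), in the authors' deposited table. Matrix and TGF-beta response genes had 8 higher and 1 lower of 15 (8 and 3 adjusted over the list alone, median 0.77, percentile 99.9). The largest changes were in TNC (3.04), LAMB3 (2.34), COL4A1 (1.55) and CTGF (1.51), with FN1 at 0.16 (q = 0.822), in the authors' deposited table. Of the markers of other cells, AQP3 (1.27, to 5.31 FPKM) and CD68 (3.19, to 110.3 FPKM) rose and SLC12A3 (-1.23), PDGFRB (-3.04) and ESAM (-2.36) fell in the authors' deposited table. The counts were 1 higher and 1 lower of 3 distal nephron markers, 0 and 1 of 3 fibroblast markers, 0 and 1 of 2 endothelial markers, 1 and 0 of 2 leukocyte markers and 0 and 0 of 1 podocyte marker, by the authors' deposited table. Adjusted over the list alone they were the same except for fibroblast markers, at 0 and 2. SCNN1A (-2.41, q = 0.301), ACTA2 (0.23, q = 0.785), CDH5 (-0.03, q = 0.949), CD14 (0.44, q = 0.387) and PODXL (0.16, q = 0.589) did not pass the test in the authors' deposited table.

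**Figure D1:**
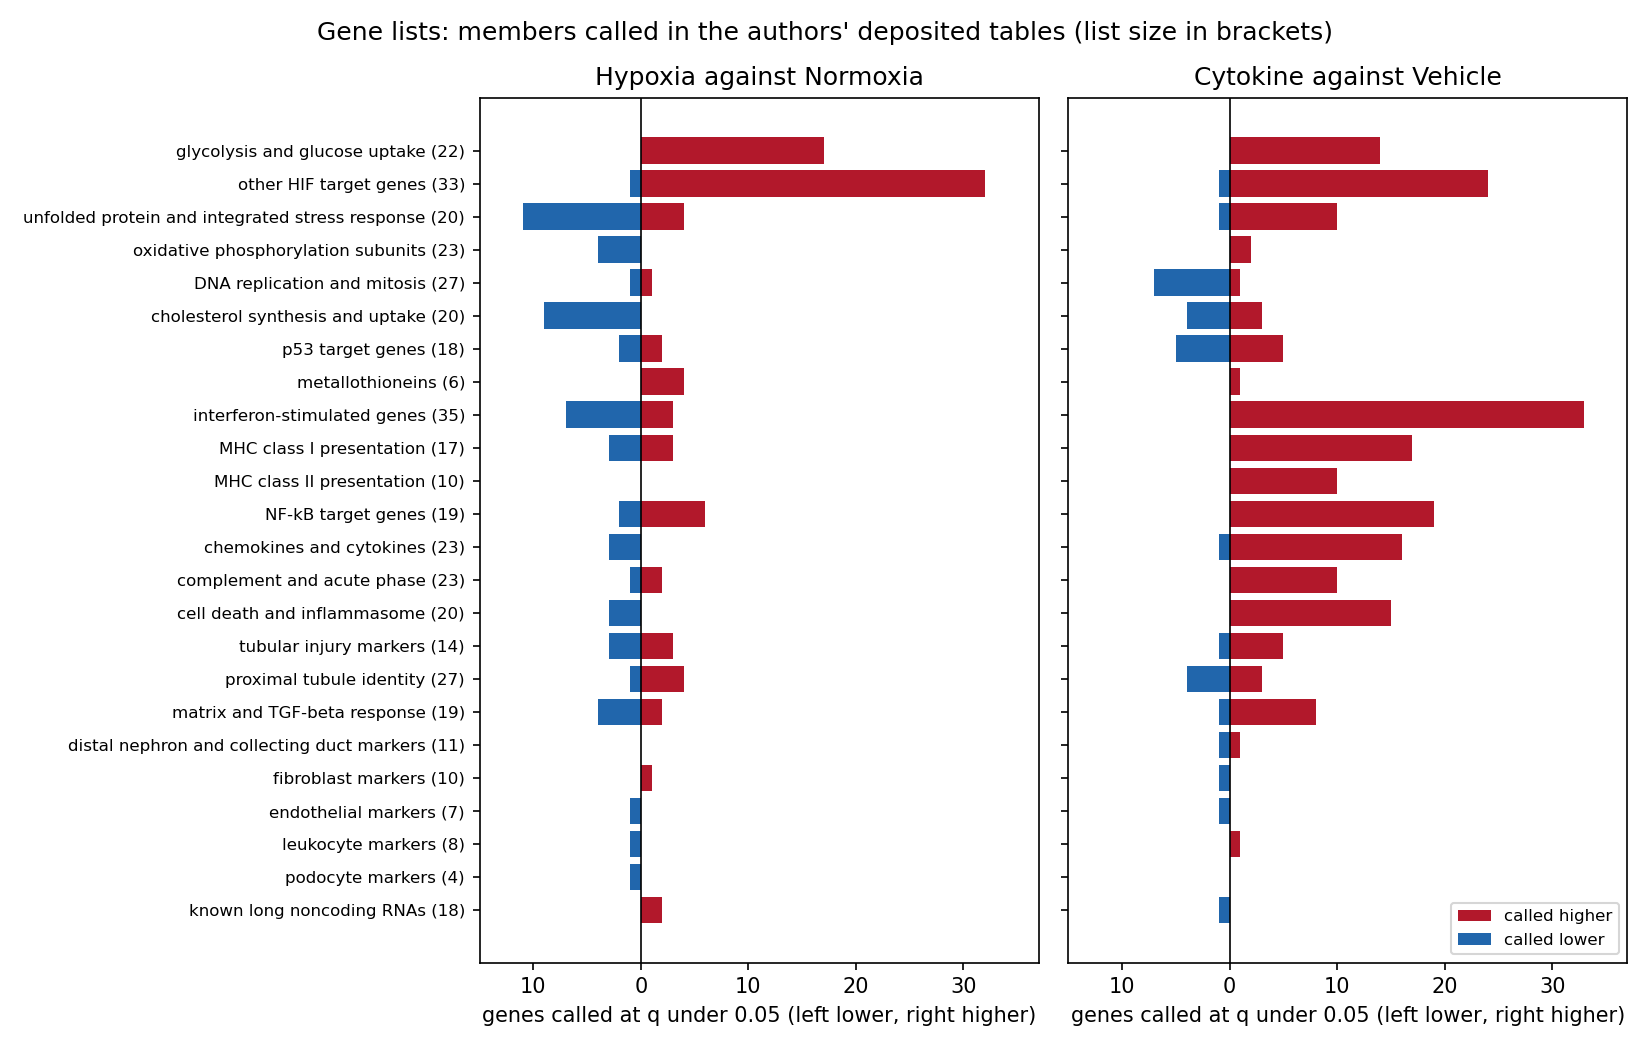
Members of each fixed gene list called higher (red, to the right) and lower (blue, to the left) at q under 0.05 in the hypoxia comparison (left panel) and the cytokine comparison (right panel), with the list size in brackets. The other HIF target genes show 32 higher in hypoxia and 24 higher with cytokines, and the interferon-stimulated genes 3 and 33.

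Of 12595 genes tested in both comparisons, 450 rose in both against 327.7 for independent lists (Fisher's exact test, one-sided, p = 4.16e-15), and 337 fell in both against 315.2 (p = 0.0780). Another 333 rose in hypoxia and fell with cytokines against 277.8 by chance (Fisher's exact test, one-sided, p = 7.72e-05), and 460 did the reverse against 371.9 (p = 3.98e-08). Called in both, whatever the direction, were 1580 against 1292.6 by chance (Fisher's exact test, one-sided, p = 1.16e-31), so the excess is not confined to shared directions. When chance was matched on expression, an alternative chosen after seeing the data, the numbers were 327.4, 296.1, 278.7 and 391.4 in the order above and 1293.6 for all called in both. Together 793 went in opposite directions and 787 in the same direction, a balance that depends on the limit: at a q threshold of 0.01, 289 rose in both, 162 fell in both and 410 went opposite ways. With a log2 fold change of at least 1 in size these counts were 115, 56 and 111. Genes are not independent replicates, so the p values describe these lists only. By smaller of both changes, the genes highest in both, a ranking chosen after the values were seen, included NEURL3 (4.16 in hypoxia, 6.54 with cytokines), FAM115C (4.24, 3.75), ANGPTL4 (6.22, 3.01) and the scavenger receptor ACKR3 (2.91, 3.79) in the authors' deposited tables. CYP1B1 (-3.09, -2.63), TUBA8 (-2.11, -2.41), TAGLN3 (-2.02, -2.17) and CLDN2 (-3.53, -1.89) fell in both by the authors' deposited tables. Of the genes named above, METTL7A (-0.68 in hypoxia) and SLC27A4 (-0.67 with cytokines) also fell in both, while SLC43A1 (0.87) and PADI3 (0.82) rose in hypoxia and fell with cytokines and MIR22HG (1.98 with cytokines) did the reverse, in the authors' deposited tables.

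The difference between both responses was tested with standard errors taken from the authors' test statistic and a normal approximation. This choice was made after seeing the data, because that statistic does not follow the deposited p values and gives wider errors. Of 12589 genes, 1546 differed after Benjamini-Hochberg adjustment at 0.05 (537 with the higher log2 fold change in hypoxia, 1009 with cytokines), and these hold 620 of the 793 opposite genes. VCAM1 (-1.92 in hypoxia and 3.41 with cytokines), CXCL1 (-2.17 and 2.06), CCL2 (-1.72 and 8.31), S1PR3 (-1.87 and 1.97) and HIF1A (-1.52 and 1.13) passed this test with the higher value with cytokines in the authors' deposited tables. SEMA5B (2.20 and -3.25), PPL (2.07 and -2.00) and KBTBD11 (2.05 and -2.38) passed it with the higher value in hypoxia in the authors' deposited tables. S1PR3, SEMA5B, PPL and KBTBD11 are outside the fixed rule. They were picked from the opposite genes that passed, by size of change, so their passing is no separate result. Of 33 HIF targets, 16, NDRG1 and CA9 among them, had the higher log2 fold change in hypoxia by the difference test and 1, TFRC, the lower. CA9 here and SLC2A3 below are outside the fixed rule and were named after their values were seen. Of 21 glycolysis genes, 3 (ENO2, PFKFB4 and SLC2A3) had the higher log2 fold change in hypoxia by this test and 0 the lower, and HK2 did not pass it. MIR22HG, called in opposite directions, did not pass it either. In the list of interferon-stimulated genes all 31 tested in both comparisons differed, with the higher value with cytokines.

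**Figure D2:**
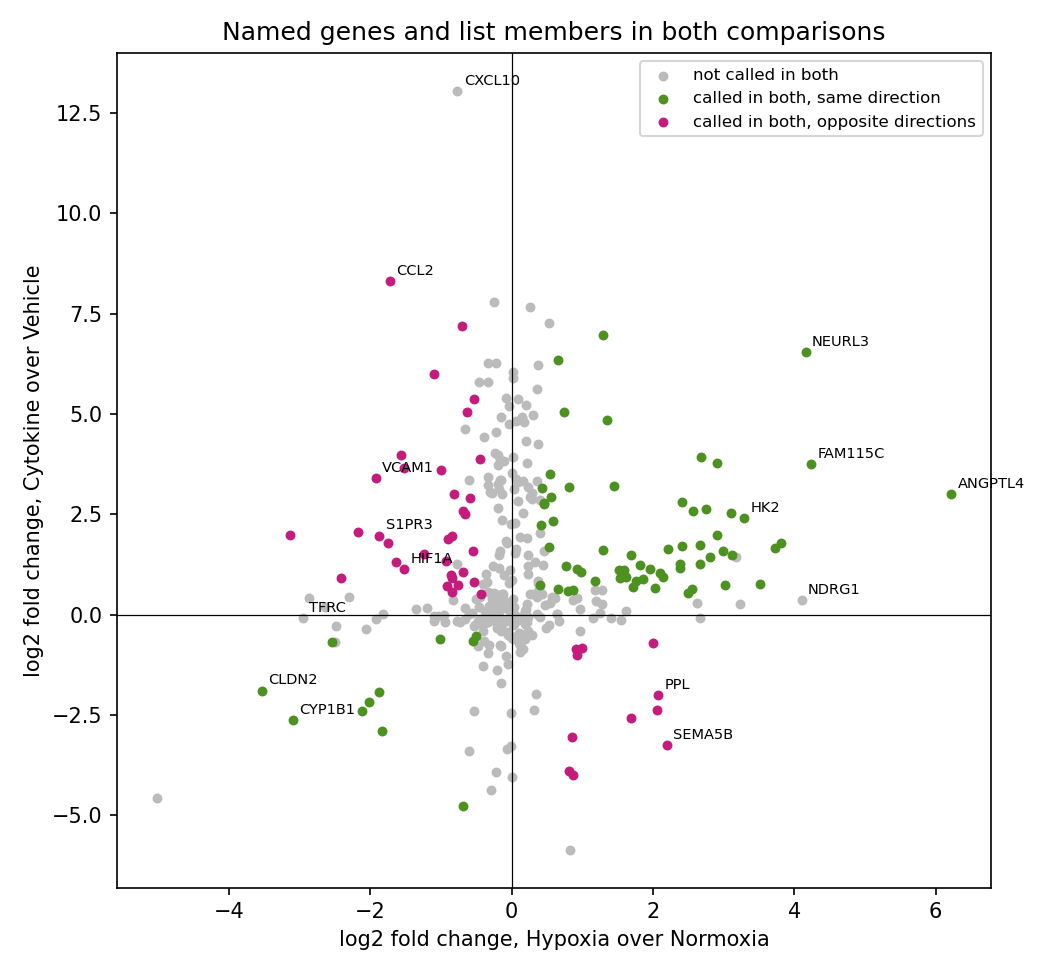
Log2 fold change in hypoxia (horizontal axis) against that with cytokines (vertical axis) for the named genes and list members tested in both comparisons, 1 point per gene, with genes called in both in green (same direction) or magenta (opposite directions) and the rest in grey. ANGPTL4 (6.22, 3.01) and NEURL3 (4.16, 6.54) lie at the upper right, VCAM1 (-1.92, 3.41) and CCL2 (-1.72, 8.31) at the upper left, and SEMA5B (2.20, -3.25) at the lower right.

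Some long intergenic noncoding RNAs (lincRNAs) of a published catalogue responded to each treatment. Of 373 catalogue loci tested in hypoxia, 44 rose and 10 fell, and of 328 tested with cytokines, 25 rose and 31 fell. Called were thus 14.5% of tested loci in hypoxia and 17.1% with cytokines, against 32.1% and 34.8% of known genes tested beside them. Most of the 4204 catalogue loci were not tested. The counts higher and lower depend on the limit. At a q threshold of 0.01 they were 25 and 5 in hypoxia and 16 and 14 with cytokines. With p values from the deposited statistic they were 12 and 1, and 8 and 7. Of 292 tested in both, 3 rose in both against 1.16 by chance (Fisher's exact test, one-sided, p = 0.0978), namely linc-UMODL1-2 (2.31 in hypoxia, 3.69 with cytokines), linc-POU5F1-1 (2.01, 1.14) and linc-CREBBP (1.45, 1.51) in the authors' deposited tables. Another 3 fell in both against 0.955 (Fisher's exact test, one-sided, p = 0.0587), namely linc-ZIC5 (-2.01, -2.02), linc-HEATR6-2 (-1.22, -1.75) and linc-B3GAT2-4 (-0.77, -1.49) in the authors' deposited tables. A further 5 rose in hypoxia and fell with cytokines against 3.61, and 1, linc-IGHMBP2 (-0.99, 3.70 in the authors' deposited tables), did the reverse against 0.308. The 5 were linc-PCM1 (1.65, -2.74), linc-CEBPB-1 (1.25, -1.41), linc-WNT8B (1.06, -0.97), linc-TMED5 (0.74, -0.89) and linc-PADI1-1 (0.64, -1.30) in the authors' deposited tables. Those outside the fixed rule were named after their values were seen. Called in both, whatever the direction, were 12 against 6.04 by chance (Fisher's exact test, one-sided, p = 0.00740), or against 7.67 when chance was matched on expression. The 5 highest in hypoxia were linc-TUBB6 (4.07, 18:12288322-12291290 in hg19), linc-AIRE-2 (3.56), linc-HMGB2 (5.81 to 52.8 FPKM, 3.19, 4:174264471-174291953), linc-ITIH2-7 (3.14) and linc-ATP13A4-8 (3.02) in the authors' deposited table. The 5 lowest were linc-RSPH1-1 (-2.30), linc-ZIC5 (-2.01), linc-SERHL2-3 (-1.59), linc-MEIS2-4 (-1.41) and linc-NLRP3-2 (-1.33), in the authors' deposited table. With cytokines the highest were linc-WDTC1 (5.83), linc-DGCR6-1 (4.53), linc-GCA-1 (4.45), linc-ARFGEF2-8 (4.02) and linc-PRICKLE2-1 (4.01) in the authors' deposited table. The lowest with cytokines were linc-PCM1 (-2.74), linc-ZFHX4-1 (32.2 to 5.10 FPKM, -2.66, 8:77318799-77509924), linc-HIST1H2AG-4 (-2.32), linc-RRP12 (-2.12) and linc-SERTAD2-4 (-2.06), in the authors' deposited table. The interval of linc-ZFHX4-1 overlaps that of RP11-706J10.1, the lowest gene with cytokines in the GENCODE table (-5.85). These are therefore not independent findings, and the sizes of their falls differ. The lincRNA names take a neighbouring gene's symbol and do not mean that gene.

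The study is known to have followed up MIR210HG, linc-ATP13A4-8 and linc-KIAA1737-2, so their direction is not independent evidence. MIR210HG, a microRNA host transcript (11:565657-568457 in hg19), rose from 4.03 to 20.9 FPKM in hypoxia (2.37, q = 0.00037) and from 2.14 to 5.90 FPKM with cytokines (1.46, q = 0.000317) in the authors' deposited lincRNA tables. The linc-ATP13A4-8 locus (3:194006427-194030593), which overlaps the LINC00887 record, rose from 2.21 to 17.9 FPKM in hypoxia (3.02, q = 0.00037) and stood at 1.28 and 1.40 FPKM in Vehicle and Cytokine (q = 0.908) in the authors' deposited tables. The linc-KIAA1737-2 locus (14:77426018-77432564) rose from 2.35 to 10.9 FPKM with cytokines (2.21, q = 0.000317) and stood at 2.58 and 2.82 FPKM in Normoxia and Hypoxia (q = 0.846) in the authors' deposited tables. In the GENCODE tables MIR210HG is split over 2 records at 1 interval: ENSG00000247095.2 rose in hypoxia (9.24 to 52.6 FPKM, 2.51) and with cytokines (1.23, q = 0.0219), and the other record stood at 0.442 and 0.918 FPKM in hypoxia (q = 0.679), by the authors' deposited tables. Of other well-known long noncoding RNAs, SNHG1 (1.25) and PVT1 (1.18) rose in hypoxia among 9 tested with 0 lower (2 and 0 adjusted over the list alone), in the authors' deposited tables. DANCR fell with cytokines (-1.29) among 8 tested with 0 higher (0 and 1 adjusted over the list alone), in the authors' deposited tables. GAS5 did not pass the test in hypoxia (0.40, q = 0.0963) or with cytokines (-0.07, q = 0.873) in the authors' deposited tables.

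**Figure D3:**
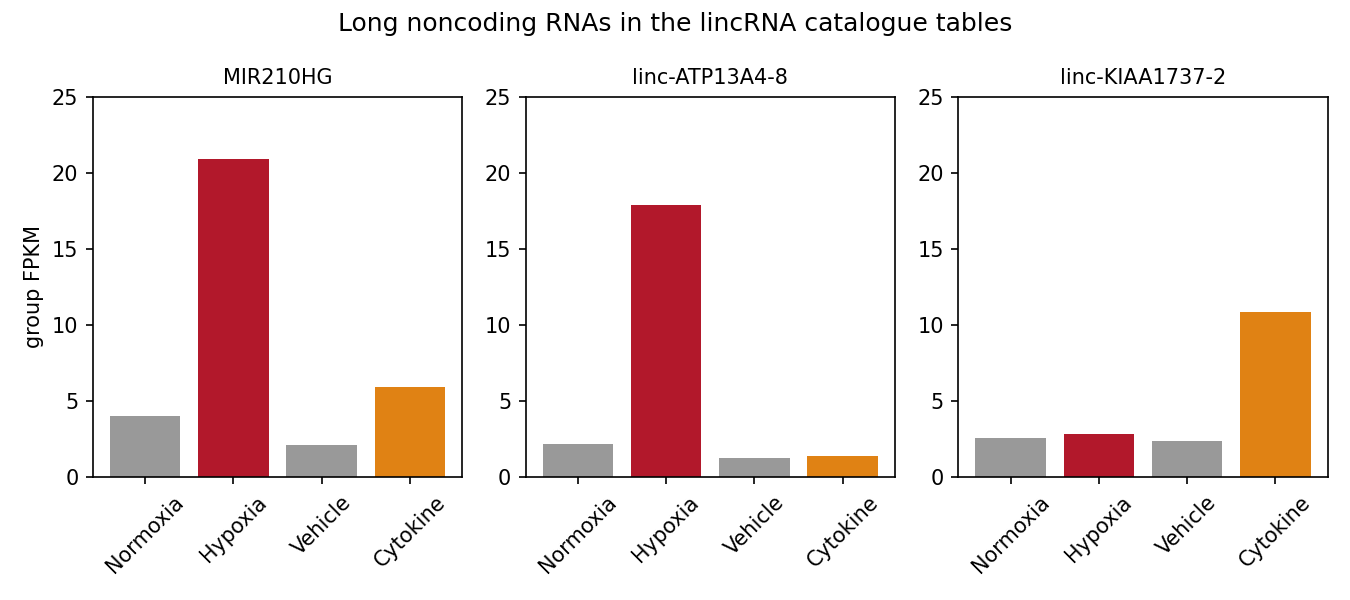
Group FPKM (vertical axis, from 0) of MIR210HG, linc-ATP13A4-8 and linc-KIAA1737-2 in the lincRNA catalogue tables, 1 bar per group and no error bars because the tables hold 1 value per group. MIR210HG is highest in Hypoxia (20.9), linc-ATP13A4-8 in Hypoxia (17.9) and linc-KIAA1737-2 in Cytokine (10.9); the Normoxia and Hypoxia bars come from another table than the Vehicle and Cytokine bars, normalized separately.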

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

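Chosen after the data were seen were the p values from the deposited statistic, the known genes of the lincRNA tables, the matched chance numbers and the test of differing responses with its alternatives. No paired analysis was possible because the deposited tables hold 1 value per group, with no value per replicate, and leaving out a replicate was not possible for the same reason. Of 58 counts under alternatives, 34 stayed within 1.5 times of their main count, centring and the 1 FPKM filter among them. At a q threshold of 0.01, lincRNAs in hypoxia numbered 25 higher and 5 lower, lincRNAs with cytokines 16 and 14, genes lower with cytokines 1235, genes higher in both 289, lower in both 162, opposite 410 and lincRNAs higher in both 1. With a log2 fold change of at least 1 in size, 673 genes rose and 517 fell in hypoxia, 1316 rose and 858 fell with cytokines, 115 rose in both, 56 fell in both and 111 went opposite ways. These follow from the construction, since a stricter limit keeps fewer genes. With p values from the statistic, 666 rose and 580 fell in hypoxia, 1212 rose and 508 fell with cytokines, and lincRNAs numbered 12 and 1 in hypoxia and 8 and 7 with cytokines; why the statistic departs from p was not tested. No alternative reversed a list median or a named gene. Of 156 list medians under alternatives, 155 kept their side of the random lists, and 1, the known long noncoding RNAs in hypoxia without a filter, moved past it (0.40). The 824 alternative values of named genes, from a pseudocount, centring and the 1 FPKM filter, kept direction and call. A pseudocount cannot change a direction or a deposited q value, and centring shifted all genes alike by a small amount. Those values could therefore hardly have differed and say little about robustness. Centring also shifts a list and its random lists alike, so it could not move a list past them. The stricter limits and the p values from the statistic were applied to counts only, and single genes named above can lose their call under them.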

Other observations

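All tests in this section were chosen after the data were seen. The predictions for carry-over and for divided reads were fixed before their own values were computed, but each replaced a weaker first test whose outcome was known. Control groups were set against each other across separately normalized tables, so only departures from the median of all expressed genes, 0.17 on the log2 scale with an SD of 0.18 across 12047 genes, are read. The list values that follow are given before that median is taken off. The glycolysis list had the largest value (0.42, percentile 100 of random lists), with 20 of 21 members above the median of all genes. Also higher in Normoxia than in Vehicle were the interferon-stimulated genes (0.39, percentile 100) and complement and acute phase genes (0.40, percentile 99.98). The unfolded protein and stress response genes (0.23, percentile 97.61) were barely so. The p53 targets (-0.03, percentile 0) and matrix genes (0.03, percentile 0.02) were lower.

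HIF target genes stood higher in Normoxia than in Vehicle, with 30 of 31 members above the median of all expressed genes. The list median was 0.41 before the median of all expressed genes (0.17) is taken off, at percentile 100 of matched random lists. This argues against a plain difference in scale, which would move all genes alike. Carry-over of Hypoxia material would need a share of 2.91% for this list, and the same share predicts an excess of 0.24 in 68 other genes raised by at least 2 in hypoxia. They showed 0.13 (quartiles -0.02 and 0.31), with 48 below their prediction, so carry-over may account for part and remains open. The first test asked only whether the HIF members left room for that share, and it went with carry-over. A different state of the 2 control cultures may also account for it and cannot be told apart, because the labels give no oxygen level, density or medium for the controls.

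HIF target genes also rose with cytokines, by a list median of 0.88. A scale difference between groups would move all genes alike, and the percentile of 100 among random lists argues against it. A low Vehicle level alone is argued against by the comparison with Normoxia, where the list still had a median of 0.58 after centring, above the middle 95% of random lists, which ended at 0.28. Of its members, 0 are on the other cytokine lists. That the higher HIF1A RNA level accounts for these genes is a hypothesis, which no test here addressed. In hypoxia the HIF1A RNA level fell (-1.52) while 32 of 33 of these genes rose, so RNA and targets did not move together there. HIF1A protein was not measured here, so these RNA values say nothing on the amount of the protein in either treatment.

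Calls of known genes differed between the GENCODE and lincRNA tables for a small set. In hypoxia 3922 were called in both tables, 21 in the GENCODE table alone and 76 in the lincRNA table alone, with 0 in opposite directions. Of those 76, 34 (44.7%, against 5.27% of all tested) lie in an interval that also holds a GENCODE noncoding record, and that percentage was the first test, which did not decide. Their treated FPKM in the GENCODE table was a median of 0.649 times that in the lincRNA table (0.440 with cytokines), in line with reads divided between records of 1 locus. For the other 42 the ratio was 0.996, which argues against divided reads there. What ended those calls was not tested.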
